A study of Mus musculus with 4 samples.

How the data were processed

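RNA from the quadriceps of FVB/N mice aged 6 to 8 weeks was sequenced, in 2 libraries from non-transgenic control muscle and 2 libraries from muscle of mice carrying a Thbs1 transgene. Groups and replicate numbers were taken from the sample titles. The labels do not say that the libraries of a group came from separate animals. The p-values of single genes therefore measure the spread between these samples, which may be technical.

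Per the submitters' processing notes, the authors used bcl2fastq, TopHat and edgeR with the mouse build mm10, and no versions are stated there. The authors deposited a table of all genes and a list of significant genes. The per-library values deposited by the authors are RPKM, reads scaled by gene model length and by the reads of the library. The authors' base means are signal values, the mean of reads divided by a size factor per library. The authors' deposited table also holds the ratio of the control to the transgenic base mean, which is below 1 for genes higher in transgenic muscle, and a p-value with an adjusted p-value for each gene. The log2 column of the deposited table was not used here, because a spreadsheet had replaced some of its cells with error text. Gene symbols that a spreadsheet had turned into dates were restored from their Entrez identifiers for 27 genes. The table lists 23482 genes, of which 5713 have no read in any library. No mitochondrially encoded gene is listed among them, so that list gave no value.

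Together, the RPKM values and the base means fix the number of reads behind each value. All values came out whole within a tolerance of 1e-06 of a read, with a largest deviation of 6.05e-09. The reads in genes were 19380650 and 18815221 in the control libraries and 20053685 and 19813029 in the transgenic libraries. The base means equal the mean of the recovered reads over median-of-ratios factors, and which tool gave the deposited p-values was not settled here. The recovered reads were used for the depth, for limma-voom and for other scalings, and the test of the text runs on the RPKM values. A count model had been planned for a file of counts. The files hold RPKM, so the test planned for normalised values was used in its place.

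Differences were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(RPKM + 1). Genes with at least 1 RPKM in at least 2 libraries were tested, which left 10015 genes. A gene below 1 RPKM in both libraries of a group entered the test through the other group, which favours a change. The test was two-sided, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 fold change is on the log2(RPKM + 1) scale, which understates the change of genes with low values, and is transgenic minus control. Each fold in RPKM is the ratio of the group means. Gene lists, 34 in all, were fixed before the data were examined, and the 30 lists with at least 3 tested members, leaving out the sex check, were tested with camera from limma at a preset correlation of 0.01 and adjusted over the lists. Camera at the preset correlation sets the members against the other genes, so its p-values do not measure the spread between libraries. Camera with an estimated correlation, camera on ranks and fry were alternatives. With the correlation estimated, camera takes its degrees of freedom from the few libraries. It then has little power, so a high adjusted p from it cannot decide on a list. The T, B and NK cell list had 0 tested members and the neutrophil list had 1, so neither was tested.

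Genes are named by a rule set before the data were examined. It takes Thbs1, the 10 genes with the largest rise and the 10 with the largest fall past the threshold with a mean of at least 1 RPKM and no clone name, up to 4 members of each list with the smallest p and all members of lists with 5 or fewer tested, and the genes of the sex check. Other genes are named as chosen after their values were seen. One gene that the rule takes is not reported here. Coordinates are from GENCODE M21 on GRCm38, the assembly called mm10. Library strandedness is not given in the sources used here, so reads of overlapping genes cannot be told apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

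The test was tried on simulated reads drawn from the means and sizes of these libraries, with 200 genes changed in each of 5 simulations. A first simulation spread replicates more widely than the libraries do, with a mean variance of 0.153 against 0.0801 in the libraries, because variation between genes was counted 2 times. The simulation quoted here, with a mean variance of 0.0689, was chosen because its spread was nearer to that of the libraries. In it, 0.8% of genes changed 1.5-fold were called, 5.2% of those changed 2-fold, 75.9% of those changed 4-fold and 90.8% of those changed 8-fold. The wider simulation gave 0.0%, 0.0%, 3.6% and 36.3%. These rates hold for few changed genes and may be too low where more genes change. Of 49126 unchanged genes tested over the 5 simulations, 29 were called. These stood beside 2, 13, 189 and 227 calls among the genes changed 1.5-fold, 2-fold, 4-fold and 8-fold. A list of 25 genes raised 1.5-fold was called in 5 of 5 simulations, and 0 of 145 random lists were called. The simulated genes varied independently of each other, so these list counts give no error rate for lists whose genes vary together.

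The alternatives tried covered scaling, tool, filter, pseudocount, threshold, replicate number, each library left out, and Thbs1 left out of library sizes and tests. Count models were kept for files deposited as counts and were not run.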

Results

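Quadriceps RNA was measured by sequencing in 2 non-transgenic control libraries and 2 libraries from mice that overexpress Thbs1, which encodes thrombospondin-1, a secreted matricellular glycoprotein. The comparison asks which transcripts change when Thbs1 is overexpressed in skeletal muscle. The libraries held 18815221 to 20053685 reads in genes. Across the 10015 genes tested, Pearson's r of log2(RPKM + 1) was 0.977 between the control libraries, 0.971 between the transgenic libraries and 0.927 to 0.942 between groups. Spearman's rho was 0.964, 0.960 and 0.895 to 0.922. These correlations are across genes, which are not independent replicates. The libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 36.8 for controls and 48.0 for transgenics, so neither is a copy of the other. Xist lay between 3.53 and 4.73 RPKM in all 4 libraries, and the Y-linked genes Ddx3y, Eif2s3y and Kdm5d were listed at 0 in all 4, while Uty had 1 read, in transgenic library 2.

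Thbs1 was at 8.61 and 12.2 RPKM in the control libraries and at 12900 and 15411 RPKM in the transgenic libraries. Its log2 fold change was 10.29 (SE 0.23, limma adjusted p = 0.000564, n = 2 per group). Thbs1 took 12.0% and 14.4% of the reads in the transgenic libraries, against 0.00802% and 0.0114% in the controls. The gene lies on chromosome 2 from 118111876 to 118127133 on the forward strand in GRCm38, and its exons overlap those of Gm29233 on the opposite strand. Reads of the transgene and of the endogenous gene were not separated here. Of the other thrombospondins, Thbs4 rose from 37.4 to 133 RPKM (log2 fold change 1.89, SE 0.38, adjusted p = 0.0483). That call was lost with median-of-ratios scaling (adjusted p = 0.054), no filter (0.111), a pseudocount of 0.1 (0.0576) and the replicate number as a block (0.0698). It was also lost without control library 2 (log2 fold change 1.35) or transgenic library 2 (log2 fold change 1.735). Thbs2, Thbs3 and Comp had log2 fold changes of 0.50, 0.66 and 0.19, and adjusted p of 0.311, 0.225 and 0.75. The family was called higher by camera (adjusted p = 0.0201, and adjusted p = 0.607 with an estimated correlation), and the call was lost without Thbs1 itself (adjusted p = 0.308).

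**Figure D1:**
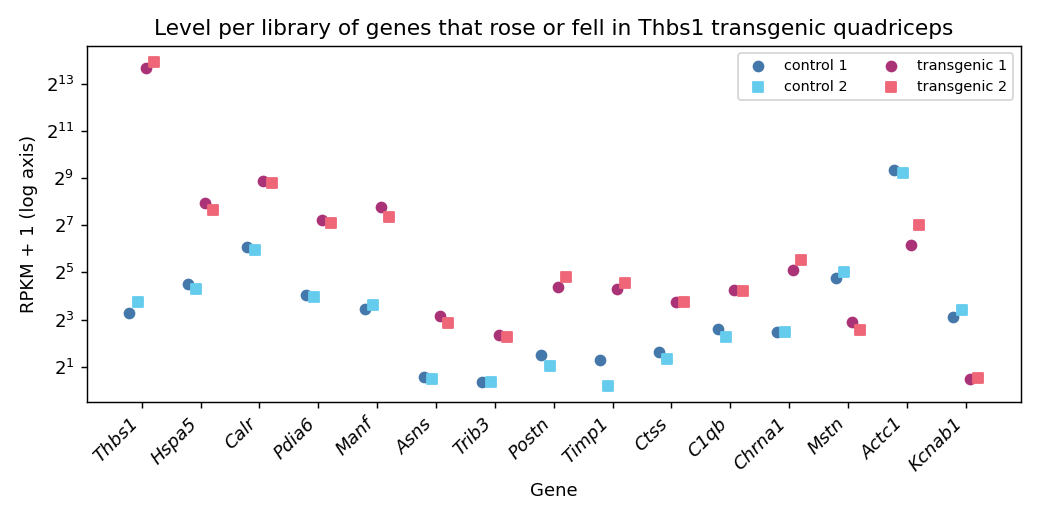
RPKM + 1 on a log axis for 15 genes that passed the limma test, with one point per library (2 control, 2 transgenic). Thbs1 stands at 12900 and 15411 RPKM in the transgenic libraries, and for every gene shown both transgenic libraries lie on the same side of both controls.

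In transgenic muscle 626 genes were higher and 122 were lower at an adjusted p under 0.05, 748 in all, or 83.7% higher. The largest rises after Thbs1 were of Rrad, a small GTPase that inhibits calcium channels, from 1.24 ± 0.847 to 54.2 ± 5.12 RPKM (SD, n = 2, log2 fold change 4.68), and of Derl3, a protein of endoplasmic reticulum associated degradation, which was at 0.0509 and 0 RPKM in the controls and 29.9 and 17.4 in the transgenics. Mt3, a metallothionein, rose 25.5-fold, Myl4, the embryonic and atrial myosin light chain, 26.8-fold, and Sln, which encodes the calcium pump inhibitor sarcolipin, 19.2-fold. Sdf2l1, Manf, Fkbp11 and Creld2, all of the endoplasmic reticulum, rose by 4.03, 4.03, 3.75 and 3.75 on the log2 scale. The largest falls were of Prima1, the membrane anchor of acetylcholinesterase, from 13.4 to 0.859 RPKM, Kcnab1, a potassium channel subunit, from 8.58 to 0.425, and Actc1, the cardiac alpha-actin, from 617 ± 45.3 to 100 ± 40.8. Mstn, which encodes myostatin, a negative regulator of muscle growth, fell from 28.7 ± 3.32 to 5.65 ± 0.993 RPKM (log2 fold change -2.16, SE 0.18, adjusted p = 0.0103). Mettl21e, Fam57b, Ppp1r1a, Rhbdl1, Wif1 and Smyd2 fell with log2 fold changes of -2.20, -1.91, -1.89, -1.65, -1.62 and -1.57, and the exons of Fam57b overlap those of the abundant Aldoa on the opposite strand. Scaling by median-of-ratios factors gave 501 higher and 247 lower genes, 67.0% higher, and moved the median log2 fold change of all tested genes from 0.10 to -0.04. Leaving out control library 2 left 1 called gene, leaving out control library 1 left 386, and leaving out transgenic library 1 left 494. The calls of Actc1, Ppp1r1a, Rhbdl1 and Wif1 were lost without either control library and with no filter on low values.

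Genes for protein folding in the endoplasmic reticulum rose together. Of the 26 tested members of the chaperone and folding list 23 rose and 0 fell, with 25 rising when adjusted over the list alone, and the list was called higher (camera adjusted p = 6.93e-18, and adjusted p = 0.607 with an estimated correlation). Hspa5, the chaperone BiP, rose from 20.1 ± 2.08 to 222 ± 35.1 RPKM (SD, n = 2), Calr, calreticulin, from 64.0 ± 4.13 to 451 ± 22.7, and Pdia6, a disulfide isomerase, from 14.9 ± 0.425 to 143 ± 8.57. Of the 39 tested genes of the ATF4 and integrated stress response list 13 rose and 0 fell, and 21 rose when adjusted over the list alone (camera adjusted p = 2.1e-07, and adjusted p = 0.607 with an estimated correlation). Asns, asparagine synthetase, rose from 0.441 to 7.02 RPKM, Trib3 from 0.277 to 3.91, and Psat1, of serine synthesis, from 0.386 to 3.55. Asns, Trib3 and Psat1 were below 1 RPKM in both controls. They passed the filter through their transgenic values, which favours a rise.

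Markers of macrophages were higher, and 14 of 15 tested rose, with 15 rising when adjusted over the list alone (camera adjusted p = 6.68e-11, and adjusted p = 0.607 with an estimated correlation). The list holds 20 genes, and 11 of the tested ones reached 1 RPKM on average in the controls. The rest may have passed the filter through their transgenic values, which would favour a rise. Ctss, cathepsin S, rose from 1.76 to 12.4 RPKM, C1qb, of complement, from 4.40 to 17.7, and Cd14 from 1.54 to 6.07. Of 34 lysosomal genes 11 rose and 0 fell, 18 adjusted over the list alone (camera adjusted p = 1.06e-06, and adjusted p = 0.607 with an estimated correlation), with Hexa, a hexosaminidase subunit, going from 11.9 to 29.8 RPKM. Extracellular matrix genes had positive fold changes in all 29 tested members, of which 7 rose and 19 rose when adjusted over the list alone (camera adjusted p = 1.94e-07, and adjusted p = 0.713 with an estimated correlation). By fry that list had an adjusted p of 0.231. Postn, periostin, rose from 1.44 to 23.1 RPKM and Bgn, biglycan, from 35.1 to 146. Control library 2 lay below control library 1 for both, at 1.04 against 1.84 RPKM for Postn and 26.6 against 43.5 for Bgn. The size of these rises therefore depends on which control is used. Of 19 TGF-beta and Smad response genes 8 rose and 0 fell, 10 adjusted over the list alone, among them Timp1 (log2 fold change 3.68) and Cdkn1a (2.38). Of these members 17 had positive and 2 had negative log2 fold changes, and Cdkn1a is also on the denervation response list. The call of that list was higher (camera adjusted p = 0.00118, and adjusted p = 0.607 with an estimated correlation).

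Of 14 denervation response genes 10 rose and 1 fell, and 11 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00015, and adjusted p = 0.607 with an estimated correlation). The acetylcholine receptor subunits Chrna1, Chrne and Chrnd rose 8.76-fold, 7.30-fold and 12.9-fold. Chrnd was at 0.296 and 0.305 RPKM in the controls, so it passed the filter through its transgenic values. Among 13 genes of embryonic myosin and regeneration 4 rose, including Ankrd1 and Nes, and Actc1 fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0216, and adjusted p = 0.713 with an estimated correlation). That call was lost without a filter on low values (adjusted p = 0.184). Of 12 immediate early genes 6 rose, 7 adjusted over the list alone, including Fos and Egr1 (camera adjusted p = 0.0157, and adjusted p = 0.65 with an estimated correlation), and the call of the list was lost without control library 1 (adjusted p = 0.34). The call of Fos (adjusted p = 0.027) was lost without control library 1 or 2 (adjusted p = 0.0593 and 0.0807) and with no filter (adjusted p = 0.0783). The atrophy ubiquitin ligase and FoxO list was not called (adjusted p = 0.0748). In it Eda2r rose with a log2 fold change of 1.71, while Mstn and Ube2b fell, giving 1 gene that rose and 2 that fell of 23, or 1 and 3 adjusted over the list alone. Eda2r was at 0.391 and 0.395 RPKM in the controls, so it also passed the filter through its transgenic values. The call of Ube2b (adjusted p = 0.0415) was lost without any one library (adjusted p = 0.06 to 0.143) and with no filter (adjusted p = 0.0836). Trim63 and Fbxo32, chosen after their values were seen, had log2 fold changes of 0.78 and 0.83 with adjusted p of 0.1 and 0.254. Proteasome subunits were called higher as a list (adjusted p = 0.0327, and adjusted p = 0.713 with an estimated correlation) with 0 of 31 members past the threshold over all genes or adjusted over the list alone, and the call was lost with median-of-ratios scaling (adjusted p = 0.241).

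Lists of fast fibre genes and of energy metabolism were lower, with few members past the test singly. Glycolysis and glycogen genes had 3 of 21 members that fell, 8 adjusted over the list alone (camera adjusted p = 6.06e-10, and adjusted p = 0.574 with an estimated correlation). Among them were Phkg1, a phosphorylase kinase subunit, and Pygm, the muscle glycogen phosphorylase, which went from 1276 ± 28.2 to 627 ± 102 RPKM (SD, n = 2). Of 16 fast fibre genes 1 fell, Atp2a1, the fast calcium pump, from 5809 ± 134 to 2570 ± 505 RPKM, and 8 fell when adjusted over the list alone (camera adjusted p = 1.33e-07, and adjusted p = 0.607 with an estimated correlation). All 45 oxidative phosphorylation genes had negative log2 fold changes, with a median of -0.41, while 0 passed the test over all genes or adjusted over the list alone (camera adjusted p = 5.13e-11, and adjusted p = 0.607 with an estimated correlation). The single calls of Atp2a1 (adjusted p = 0.0458) and Pygm (adjusted p = 0.0472) were lost with median-of-ratios scaling (adjusted p = 0.067 and 0.0614). They were also lost with no filter (0.229 and 0.136), a pseudocount of 0.1 (0.054 and 0.0535) and the replicate number as a block (0.089 and 0.0864). Without any one library both calls were lost, with log2 fold changes of -0.988 to -1.391 and -0.866 to -1.198. The call of Phkg1 was lost with no filter (adjusted p = 0.0814) and with the block (0.0604). It was also lost without control library 1, control library 2 or transgenic library 1 (log2 fold changes -1.144, -1.207 and -0.956). The medians of these 3 lists stayed below 0 under median-of-ratios scaling and without Thbs1 in the library sizes. Fatty acid oxidation (0 of 24 past the test, adjusted p = 0.0395, and adjusted p = 0.854 with an estimated correlation) and red blood cell markers (0 of 6, adjusted p = 0.03, and adjusted p = 0.713 with an estimated correlation) were called lower. Both calls were lost with median-of-ratios scaling (adjusted p = 0.0891 for each) and without control library 2 (adjusted p = 0.475 and 0.356). Without transgenic library 2 the fatty acid oxidation list turned direction (adjusted p = 0.329) and the red blood cell call was lost (adjusted p = 0.339). The 6 tested red blood cell markers are haemoglobin genes listed in pairs with the same reads, so they are not separate measurements.

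Lists for endothelial, fibro-adipogenic, adipocyte, tendon, Schwann, and smooth muscle and pericyte cells were not called (adjusted p = 0.0762, 0.0762, 0.988, 0.699, 0.887 and 0.652). Neither were slow fibre, basement membrane, integrin and dystrophin, autophagy, BMP, interferon and circadian genes (adjusted p = 0.0661, 0.216, 0.418, 0.474, 0.84, 0.71 and 0.0733). Some members of these uncalled lists passed singly. Of 14 fibro-adipogenic markers 3 rose and 0 fell, and of 11 tendon markers 3 rose and 0 fell. In the integrin and dystrophin list 2 of 26 rose and 2 fell, and in the BMP list 1 of 7 rose. In the autophagy list 1 of 30 rose and 1 fell. Among them Itga7, the muscle laminin receptor subunit, rose from 11.1 to 35.2 RPKM and Nog, a BMP antagonist, rose 3.48-fold. In all, 11 lists were called higher and 5 lower of 30, 4 of them had an adjusted p under 0.05 by fry, and 0 were called with an estimated correlation. That last setting has little power with 2 libraries per group, so it cannot decide on these lists.

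**Figure D2:**
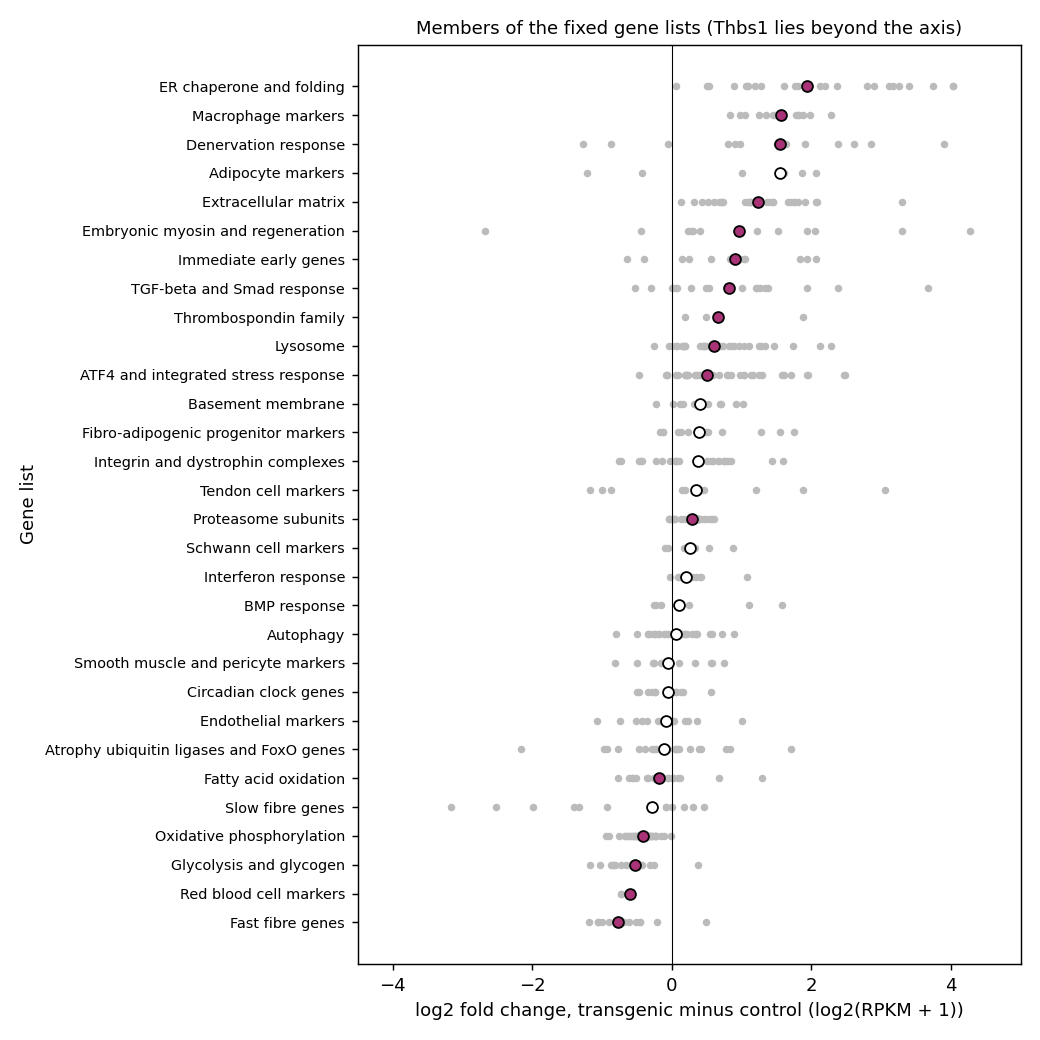
Log2 fold change of each tested member (grey) and the median (large points) for the 30 tested lists, with filled medians for lists called by camera at the preset correlation. The chaperone and folding list has the highest median, 1.93, and the fast fibre list the lowest, -0.76.

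Single libraries stood apart for some genes. Transgenic library 1 had 31.7 RPKM of Adipoq against 2.74 to 3.21 in the others, and transgenic library 2 had 1.14 RPKM of Myh7 against 66.6 to 71.1.

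**Figure D3:**
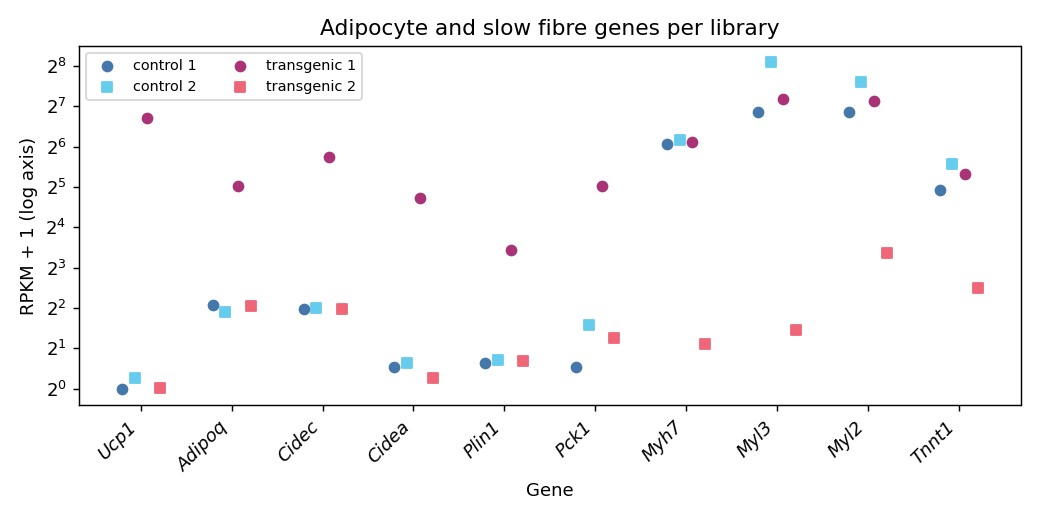
RPKM + 1 on a log axis for 6 adipocyte genes and 4 slow fibre genes, with one point per library. Ucp1, Cidea and Plin1 were chosen after their values were seen, and Ucp1 is at 104 RPKM in transgenic library 1 and at 0.207 or less in the others.

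The authors' deposited table calls 1634 genes at an adjusted p under 0.1, 987 higher and 647 lower in transgenic muscle. Of these 1395 were tested here, and all 1395 had the same sign. With limma, 1129 of them passed 0.1 and 671 passed 0.05. Both comparisons use the same libraries, so the overlap is no independent evidence.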

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

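The settings named as added were chosen after seeing the data. The log2 fold change of Thbs1 passed the threshold in every fit that held it, and of the called genes all 748 had the same sign under each setting that tested them. Each setting reuses these libraries, and genes were called because their groups separate, so the shared sign is no independent evidence. The number of changed genes moved by over 1.5 times with no filter (146, or 135 higher and 11 lower), without Thbs1 in library sizes and tests (1561, with 1458 higher), and at an adjusted p under 0.1 (1705, or 1303 higher and 402 lower). Genes lower numbered 247 with median-of-ratios factors, and 469 with limma-voom and these factors, which was added. Scaling without Thbs1 put the median log2 fold change of all tested genes at 0.26, against 0.10. Leaving out each library gave 1 to 651 changed genes, 1 to 593 higher and 0 to 104 lower. The lowest count came without control library 2, where limma found 1987 genes at an unadjusted p under 0.05, and the lone sample is assumed to vary like the other group. Of the named genes other than Thbs1, 67 lost their call without control library 2 and 36 with no filter, and no named gene with a call turned direction under any setting. With the replicate number as a block 561 genes were called, of which 64 were lower. Same-numbered libraries deviated with a correlation of 0.0742, and they share only a number. Of 16 lists called, 0 were called with an estimated correlation and 4 by fry, which does not compare a list with other genes (ATF4, chaperone and folding, glycolysis, and macrophage lists). Camera with an estimated correlation has little power with 2 libraries per group, so its 0 calls cannot decide on these lists. Lists that turned direction with a call on either side did so when a library was left out: fatty acid oxidation without transgenic library 2 (adjusted p = 0.329, with 1.64e-08 to 0.475 over the libraries left out), adipocyte markers without transgenic library 1 (adjusted p = 0.0429, with 2.18e-05 to 0.887) and interferon response without control library 2 (adjusted p = 0.0463, with 0.00546 to 0.95). Lists uncalled on both sides changed sign under further settings, among them autophagy and smooth muscle and pericyte lists by fry (adjusted p = 0.578 and 0.839). The overlap with the authors' genes was 671, and it was 1129 at 0.1, 131 with no filter, which was added, and 1 to 483 without a library, added as well. Replicate agreement, the lower r of both groups, was 0.961 with a pseudocount of 0.1 and 0.981 with no filter, both added, against 0.971. Where fewer genes, fewer samples or another threshold did not set the change, the cause was not tested. The DESeq2, edgeR exact and non-robust quasi-likelihood alternatives were kept for files of counts and not run, and library totals alone are already the scaling of RPKM. With 2 libraries per group, changes of 2-fold or less are mostly below what the test calls.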

Other observations

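The lists and tests in this part were chosen after the data were seen, apart from the limma test of each gene and the camera calls of the fixed lists. Camera values of the lists chosen afterwards were adjusted over those lists alone and are no independent evidence. Further genes of the secretory pathway moved with the folding genes. In a list of translocation, signal peptidase and oligosaccharyl transferase genes 14 of 22 rose and 0 fell (camera adjusted p = 1.25e-10, and adjusted p = 0.212 with an estimated correlation), with Spcs3 and Tram1 at log2 fold changes of 1.87 and 1.58. In a list of transport between the endoplasmic reticulum and the Golgi 13 of 28 rose and 0 fell (camera adjusted p = 9.79e-09, and adjusted p = 0.212 with an estimated correlation), led by Tmed3 at 2.58. Genes of antigen presentation by MHC class II rose in 5 of 6 cases (camera adjusted p = 1.11e-05, and adjusted p = 0.212 with an estimated correlation), with Cd74 at 6.78 and 6.89 RPKM in controls and 41.2 and 57.2 in transgenics. H2-Eb1, H2-DMb1 and H2-DMa were below 1 RPKM in both controls. They passed the filter through their transgenic values, which favours a rise. Of 3 metallothioneins Mt2 and Mt3 rose (camera adjusted p = 0.00367, and adjusted p = 0.212 with an estimated correlation), and Mt1 had a log2 fold change of 2.41 with an adjusted p of 0.111. Mt3 was already known to be among the largest rises when this list was written, so the call of the list was partly set in advance. The controls lay far apart, at 10.9 and 49.3 RPKM for Mt2 (limma adjusted p = 0.0488) and at 21.2 and 107.8 for Mt1. Cytosolic ribosomal protein genes were not called (adjusted p = 0.533), with 1 of 38 that rose.

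Transgenic library 1 held more transcripts of adipocytes than the others. Ucp1, chosen after its values were seen, was at 104 RPKM there and at 0.207 or less elsewhere, and Adipoq was at 31.7 against 2.74 to 3.21. Of the 14 fixed adipocyte markers, 7 of which reach 1 RPKM on average in the control muscle, 12 were at least 2 times the highest other library. Adipose tissue in that library may account for this. Of 15 other adipocyte genes with a read, on no fixed list, 14 were at least 2 times the highest other library as well. An effect of the transgene on adipocyte genes would raise them too, so the count cannot tell these causes apart. A first count, 15 of 17, held 2 genes whose values had been seen before, which were then left out. The fixed list was not called between the groups (camera adjusted p = 0.988), which does not exclude an effect of the transgene, and an effect seen in that library alone stays open.

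Transgenic library 2 held fewer transcripts of slow fibres. Myh7, the slow myosin heavy chain, was at 1.14 RPKM there and at 66.6 to 71.1 in the other libraries. Over 13 slow fibre genes the median log2 ratio of that library to the control mean was -1.05. A part of the muscle with fewer slow fibres cannot be told apart from a difference between animals, because only 1 library shows it. The list was not called between the groups (camera adjusted p = 0.0661), which does not exclude an effect of the transgene.

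Genes of fast fibres, glycolysis and oxidative phosphorylation had negative log2 fold changes in 80 of 82 cases, of which 4 passed the test. Reads taken up by Thbs1 are argued against as the whole cause, since the median log2 fold change moved from -0.49 to -0.28 without Thbs1 in the library sizes, still below 0. That median also lay below the range of -0.12 to 0.15 that holds 95% of 10000 random lists matched on expression. The range itself cannot test read uptake, because the scaling shifts well expressed genes nearly alike. It is also drawn from unrelated genes, which vary together less than muscle genes may. A lower share of muscle fibre RNA, with all other cells kept in proportion, would raise their markers alike. The mean log2 fold change was 1.54 for 15 macrophage markers and -0.06 for 27 endothelial and smooth muscle markers (permutation p = 1e-05, the smallest that 100000 permutations can give). That permutation treats markers as independent, though markers of the same cell type vary together, so it cannot decide on this cause. Without transgenic library 2 the camera direction of the endothelial list and of the smooth muscle and pericyte list turned from lower to higher. A lower share of muscle fibre RNA stays open, as do more macrophages and an effect of Thbs1 on the fibres. Neither macrophages nor such an effect was tested as the reason for the lower values.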
